A study of Castanea mollissima with 7 samples.

How the data were processed

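RNA was sequenced from embryos of the Chinese chestnut, Castanea mollissima, a nut tree whose seed is filled by the embryo's cotyledons. The labels describe 7 samples, numbered embryo 1 to embryo 7, made from total RNA with a plant RNA kit and a directional library kit. The sample titles carry the code ys in 6 samples and the code yh in 1. The labels do not say what either code stands for, nor whether the ys samples came from separate trees, nuts or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

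Per the series' design text and the submitters' processing notes, the authors checked reads with FastQC 0.11.9, trimmed them with Trimmomatic, aligned them with STAR 2.7.10b and normalised the result to FPKM. FPKM is fragments per kilobase of gene model, scaled by the depth of the library. The genome build, the gene annotation and the program that computed FPKM are not given in the sources used here. The deposited FPKM table lists 33991 gene models, rounded to 2 decimals, and holds 206 further columns of other runs that match no sample of this series and were not used here. Columns were assigned to samples by the run number in the sample's title. The table gives gene IDs without names, products or coordinates, and no reference annotation was used. The 27 gene lists drawn up before the data were examined (seed storage proteins, starch synthesis, late embryogenesis proteins, seed coat markers and others) matched 0 IDs, so no list was tested, and genes are given by ID alone.

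The values were compared between columns first. The columns of ys replicates 1 and 3 (embryo 1 and embryo 3) held the same FPKM for all 33991 genes, and so did those of ys replicates 2 and 4 (embryo 2 and embryo 4). Each such pair was counted as 1 library, called ys 1 and ys 2 here. This left 4 distinct ys libraries and 1 yh library. The plan had been to fit all 6 ys samples and the yh sample. Merging identical columns and filtering over the distinct libraries were thus decided after the values were seen. The titles' run numbers fall into 2 series. The planned check of a batch between the series was not possible, because both ys libraries of the first series recur in the second, which holds all 5 distinct libraries.

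The depth of each library is not stated in counts. Low FPKM values are taken to move in steps of 1 read. The relative depth of 2 libraries was therefore read from the ratio at which the highest number of low values coincided within rounding. Low values were those from 0.15 to 0.8 FPKM in both libraries. At that ratio, 176 to 263 of 1877 to 2246 low genes coincided, against a median of 60 to 82 over the ratios scanned. On simulated whole reads for 33991 genes, this recovered 5 depth ratios from 0.8 to 1.25 within 0.005. It missed the ratios tried from 1.3 upward, and at 1.3 it returned 1.015. Both simulated libraries had the same expression and whole reads, so the simulation takes the steps of 1 read for granted. Because only relative depth is known, no counting interval is given.

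The comparison of yh with ys was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) over the 18871 genes with a mean of at least 1 FPKM in the 5 distinct libraries. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. With 1 yh library, the spread comes from the 4 ys libraries alone, with 3 residual degrees of freedom, and yh is assumed to vary like them. To these limma adds 2.51 prior degrees of freedom, estimated across all genes. The p-values thus do not rest on each gene's own spread alone. The same fit was repeated with each library in turn as the single one. A simulation of the comparison drew its changed genes only from those with a mean log2(FPKM + 1) above 4 in ys. Its independent errors leave out any pairing of the ys libraries. Its call rates therefore need not hold for lower genes or for the real libraries. On simulated data for this comparison, with independent errors in 18871 genes of which 200 were changed, 76 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 3 were called, with 12 false calls.

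In addition, genes were counted in which 1 library lay at least 2-fold above the highest or below the lowest of the other libraries on the log2(FPKM + 1) scale, and pairs of libraries were compared by the number of genes at least 2-fold apart. Both counts and their alternatives were added after the data were seen and carry no test. The genes to be named were fixed beforehand: up to 10 passing genes per direction, the 15 genes with the highest mean in ys, and the 10 with the largest SD in ys among genes with a mean of at least 10 FPKM. Genes without a name were to be counted, with at most 2 IDs that rose and 2 that fell printed. The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, rescaling each library to the same total, median-of-ratios scaling, quantile normalisation, robust variance, array weights, an added 2-fold limit, and leaving out each ys library. The choices above were made before the data were examined, except where stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.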

Results

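The series describes embryo transcriptomes of Castanea mollissima as part of a larger curation of chestnut expression data. Embryos were measured here as 4 distinct libraries with the title code ys and 1 with the code yh. In the ys libraries, 24942 ± 202 gene models (SD, n = 4) had a value above 0, and 18835 ± 174 reached 1 FPKM. The yh library had 24660 and 18615, respectively. Across the 5 libraries, 22796 of 33991 gene models were above 0 in each, 17841 reached 1 FPKM in each and 6736 were listed at 0 in each. Depth was estimated from the steps of low values, a method that recovered simulated ratios only up to 1.25. Relative to ys 1, the estimate was 1.20 in ys 2, 1.12 in ys 5, 1.16 in ys 6 and 1.23 in yh, and the 10 pairwise estimates were compatible with one another within 0.003. The FPKM of a library summed to between 949293 in ys 1 and 961398 in ys 5, with 961387 in yh.

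The most abundant genes each took a small share of all FPKM. The gene with the highest level, Cm11G01270, had 15149 ± 1163 FPKM in ys (SD, n = 4) and took 1.58% ± 0.11 of all FPKM. Cm07G00159 followed with 8675 ± 939 FPKM, Cm02G01201 with 7611 ± 1709, Cm05G02712 with 5177 ± 441 and Cm01G00267 with 5134 ± 649. The 15 genes with the highest mean in ys together held 7.53% ± 0.20 of all FPKM, and 1094 ± 67 genes held the upper 50% of it. A mean of at least 1000 FPKM over the 5 libraries was reached by 58 genes, and a mean of at least 10 FPKM by 11980. The functions of these genes are not known from the table, which pairs no ID with a name.

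**Figure D1:**
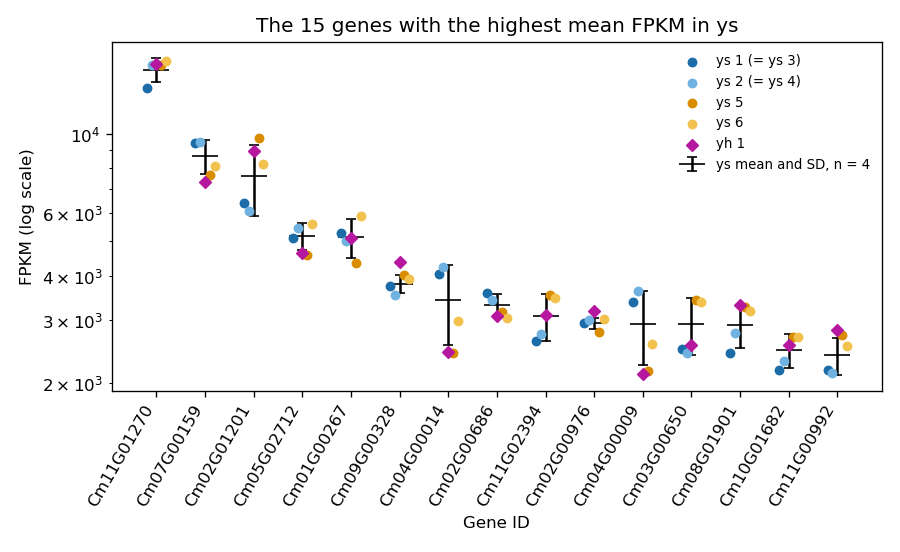
FPKM (log axis) of the 15 genes with the highest mean in ys, listed by gene ID, with 1 point per distinct library and bars for the ys mean and SD (n = 4). Cm11G01270 leads in each library, and the yh diamonds lie inside the ys range for 9 of the 15 genes.

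The same abundant genes were compared between yh and ys. The yh library lay inside the range of the 4 ys libraries for 9 of these 15 genes, above it for 4 and below it for 2. Their log2 fold changes, yh minus ys, ran from -0.46 to 0.26, and 0 of the 15 passed limma's test. The 15 genes took 7.41% of all FPKM in yh.

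The ys libraries were then compared with one another, as they share a title code. They formed 2 pairs. Between ys 1 and ys 2, 22 genes were at least 2-fold apart, and between ys 5 and ys 6, 29 genes. Across the pairs, the number was between 573 (ys 2 and ys 6) and 623 (ys 2 and ys 5). The fewest across the pairs depended on the settings: it was 990 with a pseudocount of 0.1, 159 with one of 5 and 304 with a mean of at least 5 FPKM. Pearson's r across the 18871 genes was 0.995 within each pair and 0.979 across them, with genes not being independent replicates. The yh library was nearer to ys 5 (130 genes) and ys 6 (125 genes) than to ys 1 (591 genes) and ys 2 (611 genes). Apart from embryo and run numbers, the labels give no difference between the ys samples. By run number, ys 1 and ys 2 are listed under both series, and ys 5, ys 6 and yh under the second alone. The split, and the nearness of yh to ys 5 and ys 6, thus follow this listing. No test was made between the pairs, whose estimated relative depths overlapped.

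**Figure D2:**
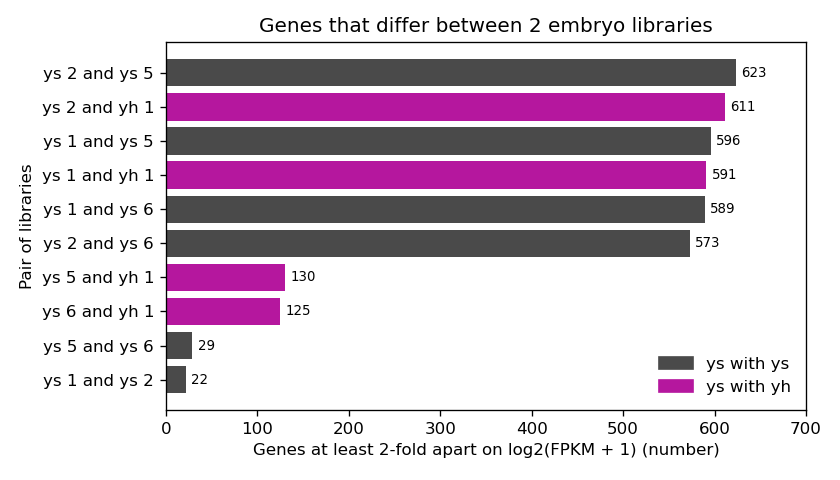
Number of genes at least 2-fold apart on the log2(FPKM + 1) scale for each of the 10 pairs of distinct libraries, with bars coloured by whether the pair includes yh. The pairs ys 1 with ys 2 and ys 5 with ys 6 have 22 and 29 such genes, yh has 125 and 130 with ys 6 and ys 5, and the other pairs have 573 or more.

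Most genes varied little within ys. Of 12006 genes with a mean of at least 10 FPKM in ys, the median SD on the log2(FPKM + 1) scale was 0.10, and 25 genes had an SD over 1. In all 25, both of ys 1 and ys 2 lay on one side of both of ys 5 and ys 6, above in 19 genes and below in 6. On the log2(FPKM + 1) scale, the level in yh was nearest to ys 5 or ys 6 in all 25. The gene with the largest spread, Cm08G01894, was listed at 0 in ys 1 and ys 2, at 233 FPKM in ys 5, at 256 in ys 6 and at 110 in yh. The second, Cm11G01944, had 125 FPKM in ys 1 and 163 in ys 2 against 9.93 in ys 5, 12.2 in ys 6 and 10.98 in yh. These genes were selected for their spread, so the size of their differences is not an estimate for other genes. With a mean of at least 10 FPKM over the distinct libraries, at most 3 genes were 2-fold apart within a pair. A spread this large could thus hardly arise except across the pairs, so the pattern of the 25 restates the split.

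Between yh and ys, 2 genes fell and 0 rose. Cm01G01752 had 0.79 FPKM in yh against 11.4 ± 0.81 in ys (SD, n = 4), a log2 fold change of -2.79 (SE 0.14, limma adjusted p = 0.029). Cm02G00179 had 11.5 FPKM in yh against 49.7 ± 3.53 in ys, a log2 fold change of -2.02 (SE 0.11, limma adjusted p = 0.029). Both were lower in yh than in all 4 ys libraries. Leaving out any 1 of the 4 ys libraries ended both calls while the fold changes stayed between -2.83 and -2.76 for Cm01G01752 and between -2.05 and -1.97 for Cm02G00179, with adjusted p-values between 0.12 and 0.24. Both calls also ended without a filter (adjusted p = 0.15, folds unchanged) and with a pseudocount of 5 (adjusted p = 0.087, log2 folds of -1.50 and -1.73), and that of Cm02G00179 ended under median-of-ratios scaling (adjusted p = 0.075, with a fold nearly unchanged). At an unadjusted p under 0.05, 741 of 18871 genes (3.93%) differed. The split of the ys libraries into 2 pairs is part of the spread of this fit and widens it, so this share cannot be set against the one chance gives. The fit also treats the 4 ys libraries as independent, which close pairs are not, so its SEs and p-values may be too small. Counting the 7 columns as 7 samples, identical ones included, would have called 15 genes.

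The single-library fit was repeated with each ys library in the place of yh to scale this count. It called 0 genes for ys 1, ys 2, ys 5 and ys 6, with 638, 669, 318 and 314 genes at an unadjusted p under 0.05 by limma. In these fits the near partner of the ys library stays in the reference group, where it widens the spread, so few calls can arise. Leaving the partner out does not lift this limit for ys 5 and ys 6. Their reference is then ys 1, ys 2 and yh, with yh 591 genes 2-fold apart from ys 1 and 611 from ys 2. With the partner left out, the fit called 1372 genes for ys 1, 1433 for ys 2, 0 for ys 5 and 0 for ys 6, the last 2 with 788 and 846 genes at an unadjusted p under 0.05. For yh against 3 ys libraries the count was 0 in each of 4 cases. Only 5 choices of a single library exist, so a share under 0.05 cannot be reached.

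By size alone, 28 genes were at least 2-fold lower in yh than in the lowest ys library and 4 were at least 2-fold higher than in the highest. These counts depend on the pseudocount: they were 85 and 10 with one of 0.1, when a ys library reached up to 44 in both directions together, and 6 and 1 with one of 5. For the ys libraries, the sum of both directions was 7 for ys 1, 5 for ys 2, 6 for ys 5 and 0 for ys 6. Each ys library has a near partner among the others and yh has none. With its partner left out, the sum was 283 for ys 1, 297 for ys 2, 34 for ys 5 and 18 for ys 6. Of these genes, 84, 120, 28 and 5 were lower, respectively. An excess of lower over higher genes was thus also seen for ys 5, but not for ys 1, ys 2 or ys 6. Against 3 ys libraries, the sum for yh was 38 without ys 1, 34 without ys 2, 51 without ys 5 and 49 without ys 6. The 28 lower genes had a median level of 12.3 FPKM in ys and log2 fold changes between -2.79 and -1.09, and 2 of them passed limma's test. The 4 higher genes had a median of 1.18 FPKM in ys and log2 fold changes between 1.16 and 2.57, and 0 passed. The largest of these, Cm02G01202, had 48.3 FPKM in yh against 7.45 ± 1.77 in ys (SD, n = 4; limma adjusted p = 0.41). Because yh was measured once, these counts carry no error.

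**Figure D3:**
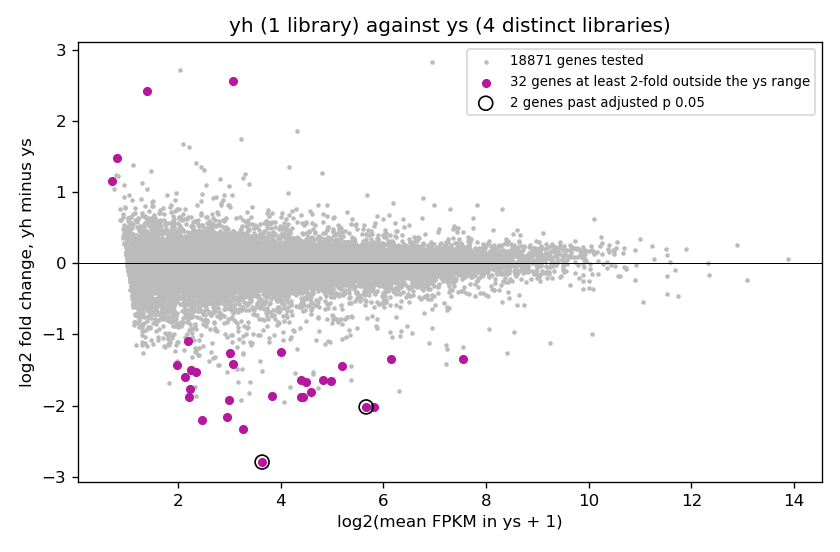
Log2 fold change of yh against ys for the 18871 genes tested, plotted against log2 of the mean FPKM in ys plus 1. Coloured points are the 32 genes in which yh lay at least 2-fold outside the ys range, 28 of them lower, and circles mark the 2 genes that passed the adjusted p of 0.05.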

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

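The tests of partners, of neighbouring IDs and of low genes in this part were chosen after the results were seen, while those of depth and scaling were set down before their values were.

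Of 61 measures examined over the 4 ys libraries, 5 had 1 library far from the other 3. The rate of about 5% that chance gives assumes unselected measures and independent libraries. Most of the 61 were selected from these data and the libraries form 2 pairs, so the count is not set against that rate. All 5 are genes in which yh lay below the ys range, named here after their values were seen. The 61 measures held all 28 genes at least 2-fold lower in yh, so this is no link between the 2 patterns. Cm08G00476 had 18.95 FPKM in ys 2 against 4.49 to 6.45 in the others. Cm10G01527 had 30.46 FPKM in ys 2 against 16.01 to 17.3, and Cm10G01528 had 52.34 FPKM in ys 2 against 20.92 to 24.91. Cm07G01362 had 43.52 FPKM in ys 6 against 21.23 to 23.89, and Cm02G02552 had 2.83 FPKM in ys 6 against 4.37 to 4.57.

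The split of the ys libraries into 2 pairs has no counterpart in the labels. Depth is argued against, since among genes with a mean of at least 10 FPKM, where low counts matter least, at least 176 genes were 2-fold apart across the pairs and at most 3 within a pair. Scaling does not account for it either, since median-of-ratios scaling and quantile normalisation left at least 556 genes across the pairs and at most 29 within. A separate preparation of ys 1 and ys 2 cannot be told apart from other causes, because these are the 2 libraries listed under both run-number series and no library of their pair was listed only once. A difference in the origin or stage of the embryos is a further candidate explanation, and no biological explanation was tested.

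The 32 genes in which yh lay at least 2-fold outside the ys range outnumber those of any ys library, the highest being 7. Low genes alone do not make up the count for yh, since among genes with a mean of at least 10 FPKM it was 15. It was at most 1 there for a ys library, but with the near partner kept, so this contrast does not measure noise alone. The lack of a near partner may account for part of the excess, and this stays open. Against 3 libraries each, with its closest library left out, ys 2 reached 297 and ys 1 283 such genes, which restates the split of the ys pairs, while ys 5 reached 34 and ys 6 reached 18. The like counts for yh, with 1 of ys 5 and ys 6 left out, were 51 and 49. Among the 28 lower genes, 6 had another of them at the next ID number, against a median of 0 and a maximum of 4 in 10000 random sets matched on mean level (one-sided permutation p = 1e-04, the smallest these sets can give). The random sets were not matched on spread within ys. No such count was made for a ys library, so the neighbours are not shown to be particular to yh. Reads shared between neighbouring copies, a local difference between genomes and co-regulated neighbours cannot be told apart here, since no gene sequences were used.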

How the results depend on the processing

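No paired analysis was possible because the labels link no ys sample to the yh sample. The 2 genes called in yh against ys were the same 2 with a pseudocount of 0.1, a mean of at least 5 FPKM, rescaling to the same total, quantile normalisation, robust variance, array weights and an added 2-fold limit. Restricting to the second run-number series leaves the same 5 libraries. Median-of-ratios scaling left 1 gene, as Cm02G00179 then had an adjusted p of 0.075 (over all alternatives 0.00084 to 0.24). By limma, a pseudocount of 5 left 0 genes (707 at an unadjusted p under 0.05) and no filter left 0 (1352), the latter with 27255 genes tested. Without 1 ys library the count was 0 in each of 4 cases, with 479 to 813 genes at an unadjusted p under 0.05 and fewer samples. Counting the identical columns separately raised it to 15. With no filter, an alternative added after the data were seen, 1 gene was called for a ys library taken as the single one. The 2 counts by size and their alternatives, like the share of the 15 leading genes without 1 library, were chosen after the data were seen. Counting all columns as separate samples was the plan, and merging the identical ones was decided after they were seen. The number of genes with yh at least 2-fold outside the ys range was 95 with a pseudocount of 0.1 (at most 44 for a ys library), 7 with one of 5, 21 with a mean of at least 5 FPKM, and 34 to 51 without 1 ys library (51 without ys 5 and 49 without ys 6). The fewest genes 2-fold apart across the ys pairs was 990, 159 and 304 under those first 3 settings; fewer genes enter under the last of them. For the other changes in the last 2 counts the cause was not tested beyond the pseudocount, which shrinks differences of low genes. The share of the 15 leading genes stayed between 7.44% and 7.60%. The fold changes of Cm01G01752, Cm02G00179 and Cm02G01202 reversed under none of these, and no scaling moved the median fold change past 0.1. The covariate for run-number series, the comparison between these series and the gene lists could not be run. Depth is known only in relative terms, which limits what can be said of genes near 0.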

Other observations

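The test in this part was chosen after the values were seen.

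Of the 30 ways in which 1 to 4 of the 5 libraries can be at 0 while all others reach 5 FPKM, 1 occurred, in 1 gene. This was Cm08G01894, at 0 in ys 1 and ys 2. Cm04G00014 and Cm04G00009, both among the 15 most abundant genes and 5 ID numbers apart, kept a ratio of FPKM between 1.12 and 1.20 in the 5 libraries while Cm04G00014 itself ranged from 2423 FPKM in ys 5 to 4237 FPKM in ys 2. Reads shared between them were not examined.

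Of the 4 genes at least 2-fold higher in yh, 2 lie close by ID to the most abundant genes. Cm02G01202 is next to Cm02G01201, and Cm11G01272 is 2 numbers from Cm11G01270. A candidate explanation is that a fixed share of reads from the abundant neighbour is counted for them. Cm02G01202 had 0.54% of its neighbour's FPKM in yh against 0.065% to 0.12% in ys, and Cm11G01272 had 0.0167% against 0.0023% to 0.0049%. A fixed share would need the neighbours to be higher in yh by as much. Cm02G01201 had 8941 FPKM in yh, above 3 of the ys libraries (6077 to 9731 FPKM), and Cm11G01270 had 15701 FPKM, also above 3 of them (13432 to 16014 FPKM). Their log2 fold changes, yh minus ys, were 0.259 and 0.055, far less than needed. The share in yh was thus 4.41 and 3.38 times the highest in ys, which argues against a share fixed across libraries for Cm02G01202. Cm11G01272 had only 2.62 FPKM in yh against 0.36 to 0.77 in ys, too near 0 to add much. A share that differs with the genome of the sample stays open and was not tested. Neither gene passed limma's test (adjusted p = 0.41 for Cm02G01202 and 0.98 for Cm11G01272).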
